A study of Mus musculus with 12 samples.

How the data were processed

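Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA. The libraries came from unstimulated B cells sorted from the spleens of female C57BL/6J mice, per the labels. Marginal zone B cells (MZB), which lie at the border of the white pulp and respond early to blood-borne antigens, were sorted as CD23-negative, CD21-high, CD1d-positive cells. Follicular B cells (FoB), which recirculate through the follicles, were sorted as CD23-positive, CD21-intermediate, CD1d-negative cells. Both gates kept B220-positive cells and left out cells with Thy1.1, F4/80, CD11b, CD93 or GL7. Each cell type was taken from mice labelled wild-type and from mice labelled knockout for the histone demethylase LSD1, encoded by Kdm1a, with 3 libraries in each of the 4 groups. In which cells the gene was deleted, and by which Cre line if any, is not given in the sources used here. Groups and replicate numbers were taken from the sample titles and genotype labels.

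The authors deposited one table of 94161 regions by 12 libraries as reads per peak in RPM over the listed regions (rppm), and every column summed to 1000000. Reads were aligned with Bowtie 1.1.1 to mm10 and peaks called with MACS2, per the submitters' processing notes. The MACS2 version, the filters on reads, the merging of peaks into one region set, any correction for the offset of Tn5 insertions, and whether coordinates count from 0 or 1 are not given in the sources used here. Coordinates are printed as deposited. The region set held 0 regions on chromosomes X, Y and M, and 92 regions on unplaced scaffolds. Regions had a median width of 339 bp (124 to 2682) and covered 38.06 Mb.

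All values in each library were whole multiples of one step within a tolerance of 0.01 (100% of values), so whole reads were recovered. The recovered totals over the regions ran from 3169966 reads in MZB knockout library 2 to 10375328 in FoB wild-type library 2, and 3 reads correspond to between 0.2891 and 0.9464 rppm. Reads without molecular identifiers are not independent molecules, so intervals and floors given here cover counting error only. The labels do not say that the libraries of a group come from separate animals, so p-values measure the spread between these libraries. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 1.08 to 1.87), so no library was counted as deposited more than once.

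Accessibility was compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a mean-variance trend) on log2(rppm + 0.5). A fold change on this scale understates the change of regions with low values. One coefficient was fitted for each of the 4 groups over the 12 libraries. Regions with at least 1 rppm in at least 3 libraries were kept, which left 89782 and removed 4379. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested regions and a threshold of 0.05, and every adjusted p of a region comes from this fit unless another tool is named. The deposited scaling was kept. As alternatives chosen after seeing the data, edgeR 4.0.16 (quasi-likelihood test, with and without TMM) and DESeq2 1.42.0 were run on the recovered reads.

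Regions were assigned to the protein-coding gene whose body overlaps them or lies nearest, from a RefSeq table of 21900 protein-coding genes on GRCm38.p6, the assembly that mm10 denotes. The table holds no strand or exons, so start sites, exons and introns were not used here. The 94069 regions on numbered chromosomes received a gene. Of all regions, 53932 (57.28%) overlapped a gene body, and the others lay a median of 26800 bp away. The planned test of promoter regions was replaced by the distance to either end of a gene (1000 and 3000 bp) and by overlap with a gene body, compared with Fisher's exact test. The planned test of sequence motifs was not run, because no genome sequence was used here.

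A total of 22 gene lists were fixed before the data were examined, as were the groups, the main test, the filter, the rule for named regions and most of the other settings tried. The lists cover the marginal zone and follicular B cell programmes, the Notch, noncanonical NF-kB and canonical NF-kB pathways, B cell receptor and Toll-like receptor signalling, the plasma cell and germinal centre programmes, migration and adhesion, B lineage transcription factors, LSD1 complex and partners, interferon response, cell cycle and housekeeping genes. They also cover markers of other cells the gates could hold, namely immature and transitional B cells, B-1 cells, T cells, myeloid cells, NK cells, erythroid cells and megakaryocytes, and dendritic cells. Some genes stand in more than one list, such as Spn in the immature and B-1 lists. Lists were tested over the regions assigned to their genes with limma's camera, a competitive test, at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the lists of one comparison, and again with an estimated correlation.

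Named regions follow one rule. Per knockout comparison they are the 10 largest increases and 10 largest decreases past the threshold whose 3 knockout values lie on one side of the 3 wild-type values, whose higher group mean is at least 4.14 rppm (the median group mean), and whose gene has a proper symbol, one region per gene. Added to these are up to 3 called regions per list with the smallest p. For the cell type comparisons the rule takes 6 regions each way, and up to 4 per marginal zone or follicular list. For the difference between cell types it takes 6 each way, and every region assigned to Kdm1a is given. Some regions that this rule takes are not reported here. Genes in clusters of near-identical copies can share reads, and their values are uncertain.

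Called regions were counted in 511 bins of 5 Mb, and bins with more calls than the genome-wide share gives (one-sided binomial test, adjusted p under 0.01 in either cell type) are termed enriched bins. This step was chosen after seeing the data. Comparisons that share libraries were set beside 10 simulations of libraries without effects. The tests of single regions and of lists were tried on simulated data with 50 regions changed at each fold size among 89782. For MZB, limma recovered 8% of regions changed 1.5-fold, 56% at 2-fold, 72% at 3-fold and 90% at 4-fold, with 16 false calls of 129. For FoB it recovered 30%, 48%, 72% and 82%, with 4 false calls of 120. For wild-type MZB against FoB it recovered 22%, 54%, 64% and 76%, with 1 false call of 109. In each of these 3 simulations camera called 0 of 20 unchanged lists. Those lists held regions simulated independently, so this does not check lists whose regions move together. The alternatives were pseudocounts of 0.1 and 2, no filter, a filter at 3 rppm, quantile and median-of-ratios scaling, fits to the compared groups alone, a replicate block, a fold threshold, robust variance shrinkage, and leaving out each library in turn.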

Results

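Chromatin accessibility was measured in marginal zone B cells (MZB) and follicular B cells (FoB) sorted from the spleens of wild-type mice and of mice labelled as LSD1 knockouts. LSD1 is a demethylase that removes methyl groups from lysines of histone H3. Each of the 4 groups held 3 libraries of 10000 sorted cells. The recovered reads over 94161 regions numbered 3705153, 3761569 and 3215626 in the wild-type MZB libraries and 4287593, 3169966 and 3383716 in the knockout MZB libraries. They numbered 3652551, 10375328 and 4188425 in wild-type FoB and 4832426, 4854978 and 3934641 in knockout FoB. Levels are given as mean ± SD over 3 libraries in reads per peak scaled to a library total of 1000000 (rppm). Fold changes are on the log2(rppm + 0.5) scale with their standard errors, and positions are on mm10. Cell type gave the main axis of variation, with 53.4% of the variance on the component that parted MZB from FoB and 9.3% on the next. Spearman correlations ran from 0.929 to 0.964 within groups and from 0.818 to 0.882 between the cell types.

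A single tested region lay at Kdm1a, the gene that encodes LSD1, on chromosome 4 from 136601890 to 136603082. Its level was 22.98 ± 6.05 rppm in wild-type and 25.05 ± 5.55 rppm in knockout MZB, and 22.77 ± 1.92 and 20.56 ± 0.061 rppm in wild-type and knockout FoB. The difference passed the test in neither cell type (log2 fold change 0.13 ± 0.16, adjusted p = 0.773 in MZB, and -0.14 ± 0.16, adjusted p = 0.866 in FoB). Which part of the gene was deleted is not given in the sources used here, so this region checks nothing about the genotype labels.

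The comparison of knockout with wild-type MZB asked which regions differ between the genotypes in marginal zone cells. The regions named first, at Steap3, Fcamr, Dbi and Lgr6, lie in stretches of chromosome 1 where calls gather, described below. Causes other than LSD1 loss stay open there. A region 26845 bp from Steap3, which encodes a ferrireductase of iron uptake, rose from 0.934 ± 0.395 to 21.8 ± 0.63 rppm (chromosome 1, 120297926 to 120298358, 16-fold, adjusted p = 3.97e-06). Within Fcamr, the gene of an Fc receptor for IgA and IgM, a region rose from 0.8357 ± 0.702 to 8.531 ± 0.558 rppm (chromosome 1, 130810068 to 130810533, log2 fold change 2.89 ± 0.35, adjusted p = 3.66e-06). A region 13328 bp from Dbi, the gene of an acyl-CoA-binding protein, fell from 29.26 ± 2.71 to 2.338 ± 0.639 rppm (chromosome 1, 120099332 to 120099952, log2 fold change -3.41 ± 0.24, adjusted p = 6.57e-12). In Lgr6, which encodes an R-spondin receptor, a region fell from 21.41 ± 2.93 to 1.583 ± 0.187 rppm (chromosome 1, 135095113 to 135095653, log2 fold change -3.39 ± 0.28, adjusted p = 6.78e-10).

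Other regions that rose were assigned to Ncald, the gene of a neuronal calcium sensor (0.6695 ± 0.355 to 8.505 ± 1.92 rppm), and, 51890 bp away, Rrm2b, which encodes a ribonucleotide reductase subunit (0.6681 ± 0.229 to 7.636 ± 1.83 rppm). A region 144994 bp from Tshz1, the gene of a zinc finger transcription factor, rose from 3.177 ± 0.515 to 17.64 ± 4.61 rppm. A region 24419 bp from Kif14, a mitotic kinesin gene, rose from 1.575 ± 0.311 to 9.126 ± 1.12 rppm, and one in the peptide transporter gene Slc15a2 rose from 3.18 ± 1.7 to 14.78 ± 2.36 rppm. A region 8907 bp from Cnr2, the cannabinoid receptor gene that helps to hold MZB in place, rose from 4.255 ± 1.3 to 21.53 ± 1.29 rppm (adjusted p = 0.00378). Sparse reads lay behind the rises at the epithelial transcription factor gene Grhl2, with 3 against 69 reads (ratio 22.7, counting interval 7.44 to 113), and at the cardiac troponin gene Tnnt2, with 3 against 47 (15.4, 4.97 to 77.5). Regions also fell at the renin gene Ren1 (13.75 ± 0.718 to 2.174 ± 0.475 rppm) and Slc66a2 (17.06 ± 3.07 to 4.363 ± 2.93 rppm). A region 94350 bp from the chemokine receptor gene Cxcr4 fell from 5.934 ± 1.63 to 0.922 ± 0.0314 rppm, and one 72890 bp from Cemip2, a hyaluronidase gene, fell from 5.194 ± 1.27 to 0.8168 ± 0.163 rppm. Decreases followed 11756 bp from Lemd1 (log2 fold change -2.23 ± 0.38) and in Brinp3 (-2.60 ± 0.43) and Rgs18, a regulator of G protein signalling (-2.00 ± 0.34). Rab7b, the gene of an endosomal GTPase, had 78 reads in wild-type and 1 in knockout MZB (ratio 79.2, counting interval 13.8 to 3170).

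Among 89782 tested regions, limma called 451 higher and 247 lower in knockout MZB (0.777%), of which 196 and 158 differed by at least 2-fold. The knockout and wild-type libraries did not overlap at 693 of the 698 called regions, and at 17.7% of tested regions against 10% by chance. These counts moved with single libraries. Higher regions numbered 204 without knockout 2, 237 without knockout 3, and 280, 290 and 238 without wild-type 1, 2 and 3. Lower regions numbered 111 without knockout 2 and 99, 109 and 83 without wild-type 1, 2 and 3. They outnumbered higher ones without knockout 1, at 360 against 357. A pseudocount of 2 gave 621 higher and 548 lower, fits to the compared groups alone 519 and 490, and quantile normalisation 780 and 474. DESeq2 called 122 higher and 48 lower, and left out Grhl2, Rrm2b and Slc66a2. It gave no adjusted p for Steap3, Tnnt2, Cnr2, Brinp3, Lemd1 and Cemip2. The Cnr2 region missed the threshold without wild-type 3 (adjusted p = 0.0569) and with a pseudocount of 0.1 (0.141). Robust variance shrinkage ended the calls of Steap3 (adjusted p = 0.114), Cnr2 (0.28) and Slc66a2 (0.154).

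Regions of immature and transitional B cell markers were higher as a group in knockout MZB, with 8 of 159 regions risen, at 4 of 10 measured genes, and 0 fallen (median log2 fold change 0.26, camera adjusted p = 1.26e-07). Adjusted over the list alone, 19 rose and 0 fell, and the call held with an estimated correlation (adjusted p = 0.0474). Of the 8 risen regions 5 were assigned to Sox4 and 1 each to Cd93, Lef1 and Spn. A region within Cd93, which encodes a surface marker of immature B cells that both sort gates excluded, rose from 19.86 ± 3.12 to 32.2 ± 5.21 rppm (chromosome 2, 148443234 to 148443770, log2 fold change 0.68 ± 0.12, adjusted p = 0.00205). Wild-type FoB stood at 35.43 ± 1.82 rppm there. A region 190693 bp from Sox4, which encodes a transcription factor of early lymphocytes, rose from 11.84 ± 0.791 to 21.13 ± 3.08 rppm (chromosome 13, 28757325 to 28758226, log2 fold change 0.80 ± 0.14, adjusted p = 0.00184), and stood at 24.08 ± 1 rppm in wild-type FoB. Lef1, a transcription factor gene of the Wnt pathway, rose by less certain amounts (log2 fold change 0.63 ± 0.16, adjusted p = 0.0387). Its call was kept only without knockout 1 (adjusted p = 0.0176) and otherwise missed the threshold without any of the other libraries (0.0543 to 0.205). The call at Spn (adjusted p = 0.0442) missed it in every fit without 1 library (0.0579 to 0.151). DESeq2 made neither the Lef1 nor the Spn call.

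Migration and adhesion genes changed both ways, with 6 of 385 regions risen and 4 fallen (10 and 8 adjusted over the list alone, camera adjusted p = 0.964). A second Cnr2 region, within the gene, rose from 5.411 ± 0.69 to 12.07 ± 2.08 rppm, and a region 103562 bp from Cxcr4 fell from 15.7 ± 0.491 to 7.034 ± 1.5 rppm. B lineage transcription factors had 7 of 1048 regions risen and 3 fallen (7 and 3 adjusted over the list alone, camera adjusted p = 0.847). Among them Tcf4, the gene of an E protein, rose from 6.847 ± 0.342 to 17.55 ± 1.19 rppm (chromosome 18, 69475659 to 69476091, adjusted p = 6.7e-05). Foxp1, a forkhead gene, fell from 23.5 ± 1.57 to 14.52 ± 1.88 rppm (adjusted p = 0.00377), a call that DESeq2 did not make. E2f2, a cell cycle transcription factor gene, rose from 18.82 ± 1.92 to 34.5 ± 1.82 rppm. Of 144 cell cycle regions 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.729).

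Marginal zone programme genes had 2 of 499 regions risen and 1 fallen (2 and 1 adjusted over the list alone, camera adjusted p = 0.847), and follicular programme genes had 1 of 322 risen and 2 fallen (1 and 3, 0.945). The latter included a region 13124 bp from Cd55, the gene of a complement regulator, with 40 reads in wild-type and 3 in knockout MZB (ratio 13.5, counting interval 4.31 to 68.4). In the Notch pathway, 1 of 283 regions rose, at Hes5, and 1 fell, at Hey1, both known Notch targets (1 and 1 adjusted over the list alone, camera adjusted p = 0.932). Hes5 missed the threshold without knockout 2 (adjusted p = 0.0604), knockout 3 (0.112) and wild-type 1 (0.148), and Hey1 passed only without knockout 3 (0.00699) and otherwise reached 0.0534 to 0.0977. Canonical NF-kB genes had 1 of 271 regions risen and 0 fallen (1 and 0 adjusted over the list alone, camera adjusted p = 0.847). The germinal centre programme had 1 of 120 and 0 (3 and 3 adjusted over the list alone, 0.847), and Toll-like receptor signalling 1 of 166 and 0 (3 and 4, 0.0675). Noncanonical NF-kB genes had 0 of 82 regions called by limma (1 risen adjusted over the list alone, camera adjusted p = 0.847). Limma called 0 regions, also adjusted over the list alone, for B cell receptor signalling (327 regions, 0.493), plasma cell (152, 0.792), LSD1 complex (141, 0.622), interferon response (68, 0.493) and housekeeping genes (58, 0.0662).

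Markers of other cells also had single risen regions in knockout MZB and 0 fallen. B-1 markers had 3 of 188 risen (5 and 1 fallen adjusted over the list alone, camera adjusted p = 0.847) and myeloid markers 3 of 81 (3 and 0, 0.77). There was 1 risen region among T cell markers, of 108 (1 adjusted over the list alone, 0.77), and 1 among dendritic cell markers, of 68 (1 adjusted over the list alone, 0.77). Of the myeloid regions Fcgr1, which encodes an IgG receptor, rose from 26.15 ± 1.33 to 39.76 ± 3.32 rppm and stood at 33.29 ± 1.96 rppm in wild-type FoB. A region 11170 bp from Adgre1, which encodes the gated-out F4/80, rose from 29 ± 1.17 to 40.86 ± 5.65 rppm and stood at 47.05 ± 3.23 rppm in wild-type FoB. Adgre1 missed the threshold without knockout 2 (adjusted p = 0.162), wild-type 1 (0.0845) and wild-type 3 (0.0801). NK cell markers had 0 of 38 regions called (3 risen adjusted over the list alone, camera adjusted p = 0.0552), and passed without wild-type MZB 1 (0.0345), knockout FoB 3 (0.0486) or wild-type FoB 1 (0.0477). Erythroid and megakaryocyte markers had 0 of 24 (1 risen adjusted over the list alone, 0.847), and the housekeeping test passed without knockout MZB 1 (0.0433) or wild-type MZB 3 (0.0485). The median, mean and test differed in sign for the follicular, Notch, plasma cell, B-1 and both NF-kB lists and for the germinal centre, T cell and dendritic cell lists. Across the 28 list regions named by rule, 9 kept their call without any 1 library and 19 did not. DESeq2 did not call 19 of the 28, among them those at Hes5, Hey1 and Adgre1, and gave no adjusted p for 1.

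The same question in FoB gave many of the same loci, and those in this paragraph lie in the stretches where calls gather. The Steap3 region rose to 25.54 ± 1.88 rppm in knockout FoB from 0.5476, 15.42 and 0.4775 rppm in wild-type 1, 2 and 3 (log2 fold change 3.36 ± 0.49, adjusted p = 9.5e-05). A region in Grhl2 rose from 0.7813 ± 0.909 to 12.17 ± 2.01 rppm (chromosome 15, 37346645 to 37347677, log2 fold change 3.51 ± 0.31, adjusted p = 2.36e-09). The region 8907 bp from Cnr2 rose from 2.367 ± 3.64 to 17.04 ± 2.02 rppm (chromosome 4, 135885753 to 135886282, 11.3-fold, adjusted p = 7.02e-06). Lgr6 fell from 11.31 ± 2.56 to 0.2907 ± 0.311 rppm (log2 fold change -3.95 ± 0.28, adjusted p = 1.88e-11), Dbi fell from 18.84 ± 6.44 to 1.817 ± 0.579 rppm, and Ren1 fell from 13.98 ± 2.36 to 1.472 ± 0.0462 rppm.

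Rises of at least 2-fold were also called at the Rrm2b region (1.108 ± 1.72 to 10.22 ± 0.427 rppm), in Ncald (0.4009 ± 0.502 to 4.261 ± 0.715 rppm) and 23397 bp from Kif14 (1.191 ± 0.642 to 6.195 ± 0.557 rppm). Tcea3, a transcription elongation factor gene, rose from 2.131 ± 2.35 to 8.593 ± 0.332 rppm, and Atp9b, a flippase gene, from 3.378 ± 1.95 to 12.35 ± 5.09 rppm. Snd1, the gene of an RNA-binding nuclease, rose from 4.311 ± 2.16 to 15.65 ± 5.71 rppm. Rpl11, a ribosomal protein gene, had a region 16648 bp away that fell from 8.287 ± 2.86 to 0.8044 ± 0.208 rppm, and Tnni1, which encodes a troponin of slow muscle, fell from 6.348 ± 2.06 to 1.334 ± 0.165 rppm. Decreases were also called at Cd55 (4.622 ± 2.42 to 0.4286 ± 0.182 rppm), Brinp3 (4.985 ± 1.33 to 0.4286 ± 0.182 rppm) and Rgs18 (4.473 ± 1.59 to 0.291 ± 0.107 rppm). Rab7b had 90 reads in wild-type and 3 in knockout FoB (ratio 22.4, counting interval 7.43 to 111). Ube2t, which encodes a ubiquitin-conjugating enzyme, rose from 0.8981 ± 1.17 to 5.217 ± 1.67 rppm (adjusted p = 0.00613) and missed the threshold without knockout 1 (0.0575), knockout 3 (0.0534) or wild-type 1 (0.0854). Slc66a2 fell from 13.34 ± 1.87 to 4.311 ± 2.58 rppm (adjusted p = 0.00448) and missed it without knockout 1 (0.0953).

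In all, limma called 287 regions higher and 197 lower in knockout FoB (0.539% of 89782), of which 122 and 83 differed by at least 2-fold. The libraries of the groups did not overlap at 480 of the 484 called regions, and at 14.7% of tested regions against 10% by chance. Higher regions numbered 147, 154 and 191 without knockout 1, 2 and 3 and 152 without wild-type 1, and lower regions numbered 118 without knockout 3 and 96 without wild-type 3. Lower regions, at 187, outnumbered higher ones without knockout 2. Fits to the compared groups alone gave 127 higher and 85 lower, and quantile normalisation gave 187 and 122. Without wild-type 2, which lay between the groups at Steap3, the counts were 363 and 138, and the log2 fold change was 4.68 at Steap3, 4.59 at Cnr2, 4.14 at Rrm2b and 4.05 at Grhl2. DESeq2 called 104 higher and 52 lower, leaving out Rrm2b, Ube2t, Tcea3, Atp9b and Slc66a2 and giving no adjusted p for Cnr2 and Steap3. Robust variance shrinkage ended the calls of Cnr2 (adjusted p = 0.16), Steap3 (0.262), Atp9b (0.188) and Slc66a2 (0.366).

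Germinal centre genes in knockout FoB had 5 of 120 regions fallen, all assigned to Rgs13, and 1 risen (5 and 2 adjusted over the list alone, camera adjusted p = 0.303). The Rgs13 region with the smallest p, at the gene of a regulator of G protein signalling, fell from 83.92 ± 1.56 to 50.42 ± 5.31 rppm (chromosome 1, 144173269 to 144174050, log2 fold change -0.73 ± 0.09, adjusted p = 4.17e-06). Migration and adhesion genes had 7 of 385 regions fallen and 2 risen (16 and 3 adjusted over the list alone, camera adjusted p = 0.303). They included a region 2432 bp from Rgs2, of the same family, which fell from 29.46 ± 4.68 to 15.81 ± 1.63 rppm (adjusted p = 0.000317). Rgs13 and Rgs2 lie in an enriched bin of chromosome 1 where 15 of 107 regions fell and 0 rose in FoB (median log2 fold change -0.4). Their falls are therefore not particular to these lists. Toll-like receptor genes had 2 of 166 regions fallen, both assigned to Cd180, the gene of a receptor related to Toll-like receptors, and 0 risen (3 and 0 adjusted over the list alone, camera adjusted p = 0.303). The first of these, 152924 bp away, fell from 1.805 ± 0.411 to 0.291 ± 0.107 rppm (adjusted p = 0.00493), a call that was lost in DESeq2 (0.271) and with a pseudocount of 2 (0.108) or the compared groups only (0.0949). B lineage transcription factors had 4 of 1048 regions risen and 2 fallen (4 and 2 adjusted over the list alone, camera adjusted p = 0.315). A region 229737 bp from Id2, the gene of an inhibitor of E proteins, rose from 8.269 ± 0.837 to 15.72 ± 2.36 rppm (adjusted p = 0.00563) and missed the threshold without knockout 1 (0.0777).

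Marginal zone programme genes had 2 of 499 regions risen in knockout FoB (0 adjusted over the list alone, camera adjusted p = 0.465), and follicular programme genes had 2 of 322 fallen, both assigned to Cd55 (2 adjusted over the list alone, 0.303). The Notch list had 1 of 283 fallen (5 fallen and 1 risen adjusted over the list alone, camera adjusted p = 0.282) and cell cycle genes 1 of 144 fallen (1 fallen and 2 risen, 0.646). Limma called 0 regions over all regions in the noncanonical NF-kB (camera adjusted p = 0.315), canonical NF-kB (0.523), B cell receptor (0.793), plasma cell (0.686), LSD1 complex (0.906), interferon (0.303) and housekeeping (0.315) lists, and 1 housekeeping region rose adjusted over the list alone. Of the marker lists, B-1 cells had 4 of 188 regions risen (6 and 1 fallen adjusted over the list alone, 0.303), while T cell (0.597), myeloid (0.512), erythroid (0.315, with 1 fallen adjusted over the list alone) and dendritic cell (0.303) markers had 0 called. NK cell markers passed the list test in FoB (38 regions, 0 called over all regions and 6 risen adjusted over the list alone, median log2 fold change 0.17, camera adjusted p = 0.00152), and lost it with an estimated correlation (adjusted p = 0.153). Immature B cell markers passed with 1 of 159 regions risen (1 adjusted over the list alone, median 0.082, camera adjusted p = 0.0162), and lost the call with an estimated correlation (adjusted p = 0.38). That list also missed the threshold without knockout 1 (0.0855), knockout 2 (0.141) or wild-type 1 (0.205). The median and the test differed in sign for the plasma cell, LSD1 complex and housekeeping lists. Of the 3 list calls in the knockout comparisons, that of immature markers in MZB alone held with an estimated correlation. Of 16 list regions named by rule, 5 (assigned to Cd55, Cnr2, Rgs13, Rgs2 and Cd180) kept their call without any 1 library. DESeq2 did not call 9 of the 16 and gave no adjusted p for 2.

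**Figure D1:**
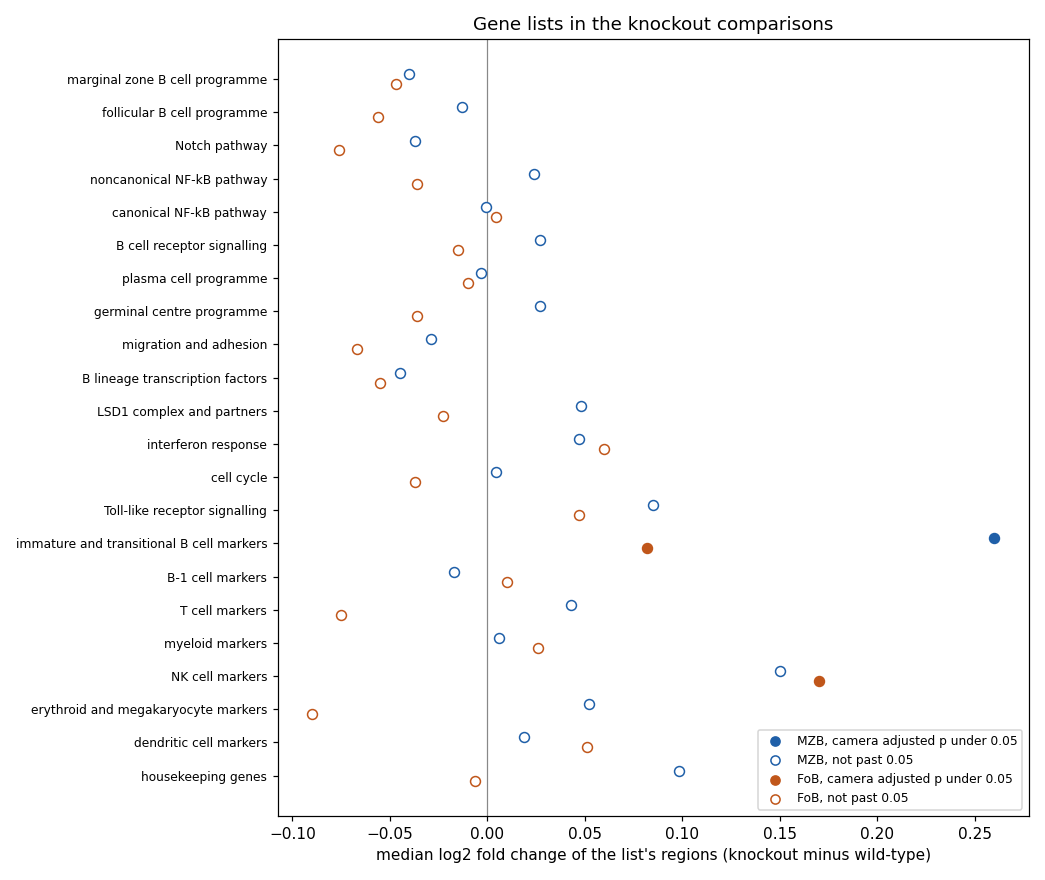
Median log2 fold change (knockout minus wild-type) over the regions of each gene list in MZB and FoB, with filled symbols where the camera adjusted p was under 0.05. Immature and transitional B cell markers were filled in both cell types (0.26 and 0.082) and NK cell markers in FoB (0.17). Both FoB calls were lost with an estimated correlation (adjusted p = 0.38 and adjusted p = 0.153).

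The knockout comparisons of the 2 cell types share no library, and they called 91 regions higher in both and 49 lower in both, against 1.4 and 0.54 by chance for independent lists, with 0 called in opposite directions. Across all tested regions, which are not independent replicates, the fold changes had a Pearson correlation of 0.24 and a Spearman correlation of 0.22. Shared regions included Steap3, Cnr2, Rrm2b, Dbi, Lgr6, Rab7b, Ren1 and Rgs18. The sign was the same in FoB at 610 (87.4%) of the regions called in MZB, and the same in MZB at 450 (93%) of those called in FoB.

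Calls gathered in 10 of 511 bins of 5 Mb. In the bin on chromosome 15 from 35 to 40 Mb, which holds Grhl2, Ncald and Rrm2b, 21 of 242 regions rose and 2 fell in MZB, and 18 rose and 2 fell in FoB. The bin on chromosome 18 from 80 to 85 Mb, with Slc66a2, Atp9b and Tshz1, had 17 risen and 8 fallen of 259 in MZB and 17 and 5 in FoB. Chromosome 1 from 130 to 135 Mb, with Fcamr, Cd55, Rab7b and Ren1, had 15 risen and 13 fallen of 347 in MZB and 13 and 11 in FoB. The next bin, from 135 to 140 Mb, with Lgr6, Tnnt2, Tnni1 and Kif14, had 13 and 11 of 274 in MZB and 6 and 9 in FoB. Steap3 and Dbi lay in the bin from 120 to 125 Mb of chromosome 1 (4 risen and 7 fallen of 81 in MZB, 4 and 6 in FoB). Rgs18, Rgs2 and Rgs13 lay in that from 140 to 145 Mb (0 and 3 of 107 in MZB, 0 and 15 in FoB). The bin of chromosome 4 from 135 to 140 Mb, which holds Kdm1a itself with Cnr2, E2f2, Tcea3 and Rpl11, had 7 risen and 6 fallen of 325 in MZB and 2 and 6 in FoB. A bin on chromosome 12 from 55 to 60 Mb had 6 risen and 0 fallen of 139 in MZB and 7 and 0 in FoB. The remaining bins lay on chromosome 18 from 75 to 80 Mb (5 and 4 of 226 in MZB, 0 and 2 in FoB) and from 85 to 90 Mb (0 and 7 of 66 in MZB, 0 and 0 in FoB).

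Together these bins held 2066 tested regions and 80 of the 140 shared calls. In MZB 7.21% of their regions were called against 0.626% elsewhere, and in FoB 5.95% against 0.412%. The bins were chosen on these counts, so the test set the 8 bins enriched in MZB against the FoB calls, which came from other libraries. In them 5.55% of regions were called in FoB against 0.435% elsewhere (Fisher's exact test, two-sided, odds ratio 13.4, p = 8.16e-70). Neighbouring regions are not independent, so this p is too small, and whether MZB and FoB libraries come from the same animals is open. Outside the enriched bins 363 regions rose and 186 fell in MZB, 220 rose and 141 fell in FoB, and 60 were shared. Tcf4, Slc15a2, Cemip2, Snd1, Sox4, Cd93 and the named Cxcr4 regions lay outside them.

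**Figure D2:**
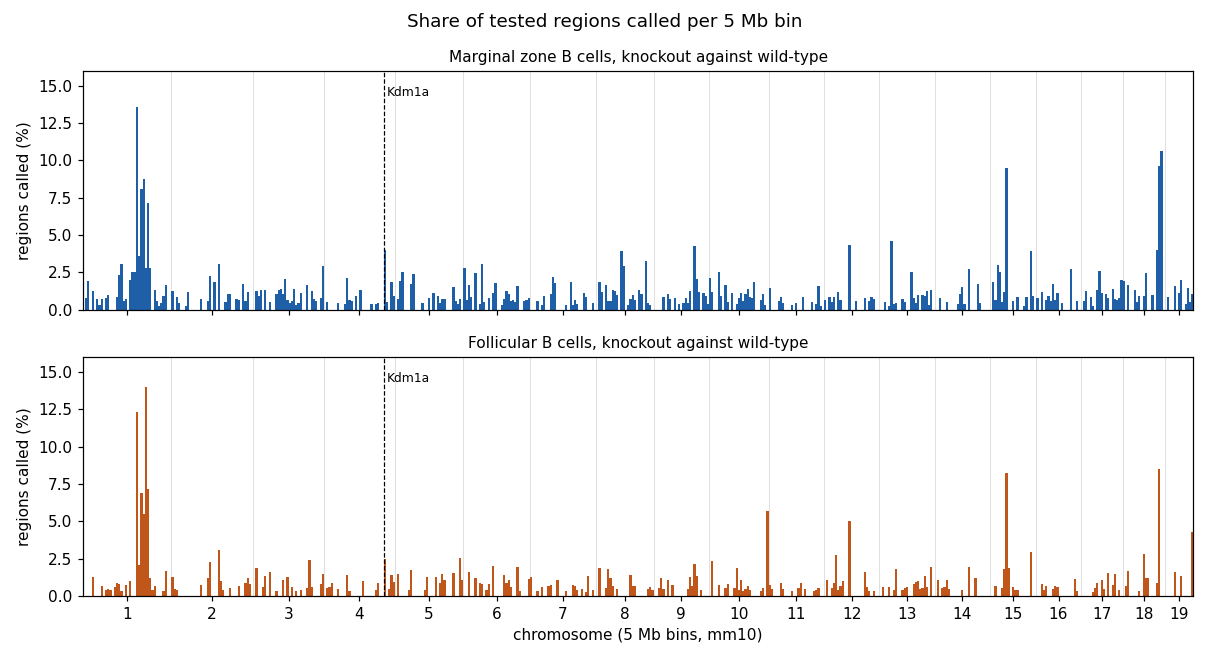
Share of tested regions called between knockout and wild-type (percent) in each 5 Mb bin along the chromosomes, for MZB and FoB, with a dashed line at Kdm1a. The bin of chromosome 15 from 35 to 40 Mb reached 9.5% in MZB and 8.26% in FoB.

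**Figure D3:**
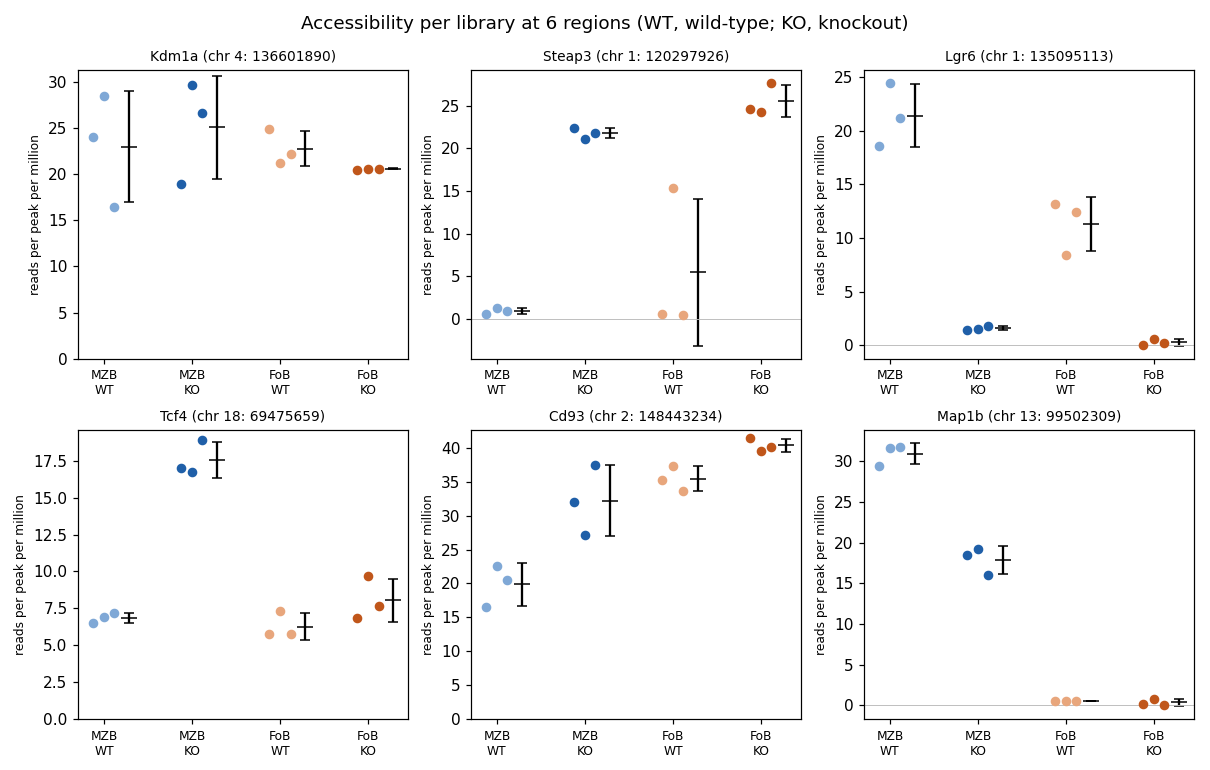
Accessibility in rppm of 1 region each at Kdm1a, Steap3, Lgr6, Tcf4, Cd93 and Map1b, with a point for each library and bars for mean ± SD (n = 3 per group). At Steap3 the wild-type FoB library 2 stood at 15.42 rppm, between the other wild-type libraries and the knockout libraries.

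Whether the knockout effect differed between MZB and FoB was tested directly. A region in Ccdc93, on chromosome 1 from 121461682 to 121462971, fell in FoB from 74.64 ± 7.84 to 32.25 ± 4.13 rppm (adjusted p = 2.72e-10). In MZB it measured 84.64 ± 3.2 rppm in wild-type and 66.61 ± 2.15 rppm in knockout (adjusted p = 0.0864), and the effects differed by 0.86 ± 0.14 on the log2 scale (adjusted p = 0.0288). It was the only 1 of 89782 regions past the threshold in limma, with 5585 at an unadjusted p under 0.05, while edgeR called 2, DESeq2 called 1, and limma called 5 with the block by genotype and number or a pseudocount of 2, 4 with quantile normalisation and 0 with a pseudocount of 0.1. The Ccdc93 call was lost without MZB knockout 1 (adjusted p = 0.0585) or 2 (0.0733), MZB wild-type 1 (0.0883), 2 (0.12) or 3 (0.237), FoB knockout 3 (0.0904) and FoB wild-type 1 (0.154) or 3 (0.165). The number of regions called was 0 in each of these fits, 3 without MZB knockout 3, 4 without FoB knockout 1, 2 without FoB knockout 2 and 3 without FoB wild-type 2. For none of the 22 lists did camera find a difference between the cell types (lowest adjusted p = 0.132, for immature B cell markers with a median of 0.12), and the signs of median, mean and test differed for the interferon and myeloid lists.

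Wild-type MZB and FoB were compared to describe the cell types themselves. A region in Map1b, which encodes a microtubule-associated protein, stood at 30.92 ± 1.31 rppm in MZB and 0.5023 ± 0.0392 rppm in FoB (chromosome 13, 99502309 to 99502855, log2 fold change 4.97 ± 0.28, adjusted p = 4.29e-16). A region was also higher in MZB at Prkdc, the gene of the catalytic subunit of DNA-dependent protein kinase (28.62 ± 4.39 against 0.6075 ± 0.528 rppm). Fam149a (25.96 ± 3.92 against 0.4753 ± 0.2 rppm) and the dopamine receptor gene Drd5 (24.27 ± 3 against 0.6936 ± 0.227 rppm) followed. A region 286662 bp from Cxcr4 stood at 23.31 ± 4.06 against 0.5279 ± 0.463 rppm. Regions in Gpatch2 (2.097 ± 1.01 against 28.51 ± 2.78 rppm) and 22621 bp from Serp2 (3.227 ± 0.957 against 39.66 ± 3.57 rppm) were lower in MZB. So were Tnfrsf8, a receptor gene of the tumour necrosis factor family (1.68 ± 0.183 against 19.43 ± 1.43 rppm), and a region 36329 bp from the nuclear receptor gene Esrrg (1.009 ± 0.516 against 11.93 ± 1.59 rppm). A region 96625 bp from Tent5a had 2 reads in MZB against 105 in FoB (ratio 30.8, counting interval 8.31 to 258), and Sun1 had 3 against 82 (16, 5.3 to 79.3). The region in Map1b stood at 17.88 ± 1.71 rppm in knockout MZB and 0.3436 ± 0.429 rppm in knockout FoB.

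Marginal zone programme genes had 186 of 499 regions higher and 68 lower in wild-type MZB (190 and 69 adjusted over the list alone), which did not set the list apart from other regions (median log2 fold change 0.31, camera adjusted p = 0.125). Among them Cd9, a tetraspanin gene, stood at 77.84 ± 6.85 against 19.65 ± 3.13 rppm, and Dtx1, a Notch target, at 33.23 ± 4 against 4.411 ± 1.16 rppm. A region 141727 bp from S1pr1, which encodes a sphingosine phosphate receptor that holds MZB in place, stood at 23.81 ± 2.35 against 2.635 ± 0.331 rppm. Follicular programme genes had 73 of 322 regions lower and 43 higher (the same numbers adjusted over the list alone, median -0.12, camera adjusted p = 0.000766), a call lost with an estimated correlation (adjusted p = 0.098). Fcer2a, which encodes CD23 and was part of the sort gate, stood at 26.49 ± 5.11 rppm in MZB and 63.43 ± 5.49 rppm in FoB. Bach2, the gene of a repressor of plasma cell fate in the follicular list, had a region higher in MZB (27.96 ± 1.15 against 5.825 ± 0.42 rppm).

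Immature B cell markers also stood lower in wild-type MZB, with 49 of 159 regions lower and 17 higher (50 and 17 adjusted over the list alone, median -0.22, camera adjusted p = 2.71e-05, and adjusted p = 0.0663 with an estimated correlation). Noncanonical NF-kB genes had 20 of 82 lower and 6 higher (19 and 6 adjusted over the list alone, camera adjusted p = 0.00325, and adjusted p = 0.098 with an estimated correlation). Housekeeping genes had 17 of 58 lower and 7 higher (18 and 8 adjusted over the list alone, camera adjusted p = 0.0178, and adjusted p = 0.098 with an estimated correlation). B lineage transcription factors (178 lower and 167 higher of 1048, 172 and 163 adjusted over the list alone) had a camera adjusted p of 0.0211, and an adjusted p = 0.239 with an estimated correlation. B cell receptor genes (48 and 44 of 327, 46 and 42 adjusted over the list alone) had 0.0275, and an adjusted p = 0.329 with an estimated correlation. B-1 markers stood higher in MZB, with 77 of 188 regions higher and 21 lower (82 and 21 adjusted over the list alone, camera adjusted p = 0.0178, and adjusted p = 0.19 with an estimated correlation). Myeloid markers had 32 of 81 higher and 4 lower (34 and 4 adjusted over the list alone, camera adjusted p = 0.0178, and adjusted p = 0.0663 with an estimated correlation). Dendritic cell markers had 31 of 68 higher and 6 lower (32 and 7 adjusted over the list alone, camera adjusted p = 0.0275, and adjusted p = 0.0826 with an estimated correlation). None of the list calls between cell types held with an estimated correlation. The median or mean differed in sign from the test, which is relative to all regions, for the B cell receptor, B lineage, housekeeping, canonical NF-kB, germinal centre, migration, LSD1 complex, interferon, cell cycle, Toll-like receptor and T cell lists. The lowest camera adjusted p among the lists not named was 0.0818, for the cell cycle.

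In total 21757 regions were higher and 10269 lower in wild-type MZB (35.7% of 89782), and the groups did not overlap at 46.7% of regions against 10% by chance. The share of called regions that were higher was 67.9% with the deposited scaling, 52.2% with median-of-ratios scaling, 49.5% with quantile normalisation, 51.6% in edgeR with TMM and 52.4% in DESeq2. The median of all regions lay at 0.18 with the deposited scaling, 0.04 with median-of-ratios scaling and -0.085 with quantile normalisation, so the levels above are relative to these. All 20 regions named by rule kept their call without any 1 library and in DESeq2.

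Between knockout MZB and knockout FoB, 20846 regions were higher and 8503 lower in MZB (32.7%), and the groups did not overlap at 42.3% of regions against 10% by chance. The region in Map1b stood at 17.88 ± 1.71 rppm in MZB and 0.3436 ± 0.429 rppm in FoB. A region 245885 bp from the homeobox gene Hlx stood at 28.12 ± 4.51 and 0.7351 ± 0.515 rppm, and one in Kalrn, an exchange factor gene, at 18.86 ± 4.58 and 0.3603 ± 0.227 rppm. Slc7a11, the cystine transporter gene, had 140 reads in MZB and 1 in FoB (ratio 176, counting interval 31.1 to 7000). Regions at Gpatch2 (2.091 ± 0.445 against 27.44 ± 1.11 rppm), Tnfrsf8 (3.121 ± 1.01 against 20.13 ± 3.3 rppm) and Wwox (0.8102 ± 0.446 against 6.539 ± 0.33 rppm) were lower in MZB. Antxr2, an anthrax toxin receptor gene, was lower too (1.86 ± 0.829 against 11.39 ± 1.39 rppm). S1pr1 (23.55 ± 3.67 against 1.525 ± 0.471 rppm) and Cd9 (74.43 ± 4.7 against 21.51 ± 2.84 rppm) were higher. The share of called regions that were higher was 71% with the deposited scaling, 54.5% with median-of-ratios scaling, 53% with quantile normalisation, 52.9% in edgeR with TMM and 55.1% in DESeq2.

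Follicular programme genes again stood lower in knockout MZB (60 lower and 41 higher of 322, and as many adjusted over the list alone, camera adjusted p = 0.00723), a call lost with an estimated correlation (adjusted p = 0.209). Immature B cell markers (31 and 15 of 159, 29 and 14 adjusted over the list alone, 0.00723) and noncanonical NF-kB genes (15 and 8 of 82, 14 and 6 adjusted over the list alone, 0.0314, with a mean of 0.032) were lower too. Both calls were lost with an estimated correlation (adjusted p = 0.186 and adjusted p = 0.251). B-1 markers were higher (72 higher and 21 lower of 188, 83 and 27 adjusted over the list alone, 0.0314, and adjusted p = 0.292 with an estimated correlation). Myeloid markers were higher too (31 and 1 of 81, 33 and 1 adjusted over the list alone, 0.0149, and adjusted p = 0.0717 with an estimated correlation). Marginal zone programme genes had 177 of 499 regions higher and 55 lower (189 and 59 adjusted over the list alone, camera adjusted p = 0.07). The median or mean differed in sign from the test for the noncanonical and canonical NF-kB, B cell receptor, germinal centre, migration, B lineage, LSD1 complex, interferon, cell cycle, Toll-like receptor and housekeeping lists.

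Regions that changed in knockout MZB were set against the wild-type difference between the cell types. Of 374 regions called in both comparisons, 317 (84.8%, exact binomial interval 80.7 to 88.2) had opposite signs, with 208 risen in knockout MZB and lower in wild-type MZB than FoB, and 109 fallen and higher. Such intervals treat regions as independent. Serp2 rose from 3.227 ± 0.957 to 10.3 ± 2.51 rppm against 39.66 ± 3.57 rppm in wild-type FoB (adjusted p = 6.21e-07), while Gpatch2 stood at 2.097 ± 1.01 and 2.091 ± 0.445 rppm. Both comparisons use the wild-type MZB libraries, and simulated libraries without effects gave a Pearson correlation of -0.54, against -0.29 observed. The simulated covariance was -0.0502 and the observed covariance -0.0894, and independent lists would share 111 regions with opposite and 138 with the same sign. Against the difference between knockout MZB and knockout FoB, which shares the knockout MZB libraries in the same direction, 148 of 296 regions (50%, 44.2 to 55.8) were opposite, and the covariance was 0.0403 against a simulated 0.05. For the FoB knockout effect the opposite share was 36% (30.6 to 41.7) against the wild-type and 58.7% (52.6 to 64.6) against the knockout difference. Without wild-type MZB 1, 2 and 3 the share was 89.8%, 90% and 90.1%, and without wild-type FoB 2 it was 79.8%.

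Called regions lay away from gene ends more often than other tested regions in 3 of the 4 sets, and off gene bodies in the risen sets alone. Regions that rose in knockout MZB lay within 3000 bp of an end of a protein-coding gene in 16.5% of cases against 25% of other regions (Fisher's exact test, two-sided, adjusted p = 0.000223). They overlapped a gene body in 48.8% against 57.7% (adjusted p = 0.000601). Regions that rose in knockout FoB did so in 15.3% against 25% (adjusted p = 0.000553) and 48.8% against 57.7% (adjusted p = 0.00814). Within 1000 bp the shares were 12.7% for MZB and 12.2% for FoB against 17.2% (adjusted p = 0.0238 and 0.0474). Regions that fell in knockout MZB lay within 3000 bp in 17.4% against 25% (adjusted p = 0.015), without a difference past the threshold within 1000 bp or over gene bodies (adjusted p = 0.192 and 0.365). Regions that fell in knockout FoB showed no difference past the threshold, with 23.4% within 3000 bp (adjusted p = 0.816) among 12 tests adjusted together.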

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

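The tests of bins, linked DNA, mixed genotypes, swapped labels, FoB cells and shared libraries were chosen only after the result was seen; the thinning of reads and the refits for Ccdc93 were not. A region in Ccdc93 stood out because the knockout effect differed between the cell types, by 0.857 on the log2 scale (standard error 0.138, limma adjusted p = 0.0288). It lies in an enriched bin of chromosome 1, and the adjusted p ran from 0.0029 without FoB wild-type 2 to 0.237 without MZB wild-type 3. With a pseudocount of 0.1 it was 0.0843.

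Knockout calls gathered in a few 5 Mb bins in both cell types. A copy number change of whole bins is argued against in 7 of the 10 bins, where the 95% intervals of the median log2 fold change reached no farther from 0 than -0.14, against -0.77 or lower for one lost and 0.5 or higher for one gained copy. Shorter changes were not tested. Most calls of the chromosome 12 bin lay in 1 short stretch, described below, which the median of the whole bin cannot show. In the other 3 bins it cannot be told apart from other causes, because the medians lay between no change and one lost copy (-0.3 in MZB and -0.19 in FoB on chromosome 1 from 120 Mb, -0.43 and -0.4 from 140 Mb, and -0.46 and -0.24 on chromosome 18 from 85 Mb). Of 450 bins that were not enriched, 6 had a median of -0.3 or lower in MZB (lowest -0.68) and 0 in FoB (lowest -0.25), so of these medians only that in FoB from 140 Mb lay below all of them. DNA linked to the targeted allele that differs from the wild-type animals' stays open on chromosome 4. Regions within 5 Mb of Kdm1a were called more often than all other tested regions in MZB (odds ratio 2.24, Fisher's exact p = 0.00993), a difference that missed the threshold in FoB (1.98, p = 0.072), and neighbouring regions are not independent. Segments of another strain's DNA on chromosomes 1, 12 and 15, and on 18 where shared, cannot be told apart from the knockout. The knockout libraries would carry both. Of MZB calls there 98.5% had the same sign in FoB, against 84.5% outside the bins. The signal did not follow the label in every library. FoB wild-type 2 lay 0.41 of the way to knockout on chromosome 1 and 0.28 on chromosome 15. On chromosome 18, set against the rest of its group, knockout 2 lay 0.44 of the way to wild-type in both cell types. Knockout 1 lay at -0.51 in MZB and -0.69 in FoB. A chromosome 18 segment that differs among the knockout animals is open too: knockout MZB and FoB libraries of the same number correlated at 0.68, 0.55 and -0.33, and the criterion first set, that all 3 be high, was not met by number 3 (highest of other pairs 0.28), whose libraries hardly deviate, while a direct effect of LSD1 loss at these regions was not tested.

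The library labelled FoB wild-type 2 lay between the other wild-type and the knockout libraries at regions called 2-fold in MZB, within and outside the enriched bins. Its greater depth is argued against, since after thinning to the depth of the shallowest FoB library it still lay 0.28 of the way to knockout (interval 0.21 to 0.35), and a whole swap of labels is argued against by the upper bound of 0.37 before thinning. Reads of both genotypes, from a heterozygous or mixed sample, may place it there, at a fraction of 0.31 (0.25 to 0.37) where the other wild-type FoB libraries had -0.22 and -0.15. Each library was set against the rest of its group, so wild-type 2 itself pushes those negative values below 0, and they are no separate check. FoB wild-type 2 is not the only library between the genotypes: toward wild-type, FoB knockout 3 lay at 0.22 (0.13 to 0.33) outside the enriched bins, and FoB and MZB knockout 2 each at 0.44 on chromosome 18. A mixed FoB wild-type 2 cannot be told apart from other differences of that animal, because the fraction was 0.41 on chromosome 1, 0.52 on chromosome 4, 0.28 on chromosome 15, 0.29 on chromosome 18 and 0.3 (0.23 to 0.38) outside the enriched bins, and none of 4 mixing targets tried gave a shared fraction. No biological explanation was tested, since the labels give none for a single library.

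Knockout MZB regions shifted toward the FoB level, by an amount that depends on the comparison. The wild-type MZB libraries that both comparisons share are argued against as the whole source, because the covariance with the simulated covariance subtracted was -0.0392. It was -0.00968 against the difference between knockout MZB and FoB, which does not use them, not far from the -0.00554 and -0.00445 of the FoB knockout effect, so the size of the shift is uncertain. FoB cells in the knockout MZB sort cannot be told apart from a change of the cells themselves, because the estimates disagree. Knockout MZB lay 0.13 (0.12 to 0.14) of the way to FoB at regions open in MZB and 0.12 (0.076 to 0.17) at regions open in FoB, with intervals over regions alone. Per library, knockout and wild-type differed by 0.14 at regions open in MZB, with knockout 1 at 0.15 and the others at 0.066 and 0.06, and by 0.065 at regions open in FoB (exact permutation p of 0.1 each, the smallest that 3 against 3 libraries allow). The CD23-negative, CD21-high, CD1d-positive gate is set to leave out FoB cells, but how far it did so in these sorts was not tested. Levels at strongly follicular regions were mixed, at 3.227 rppm in wild-type and 10.3 rppm in knockout MZB for Serp2 (39.66 rppm in wild-type FoB, adjusted p = 6.21e-07 for the knockout), 1.68 and 3.121 rppm for Tnfrsf8 (19.43 rppm, not called, adjusted p = 0.116) and 2.097 and 2.091 rppm for Gpatch2 (28.51 rppm). An effect of LSD1 loss on marginal zone identity stays open and untested.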

How the results depend on the processing

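Count tests (edgeR, DESeq2), results outside the enriched bins, genes from the nearest gene end, and shared calls, opposite signs and list calls without 1 library were chosen after the data were seen. No named region that was called changed direction in any setting run. The Kdm1a region, which was not called, changed sign without 1 library in MZB (log2 fold change -0.085 to 0.318) and between wild-type cell types (-0.187 to 0.198). Lower regions outnumbered higher ones between wild-type cell types with quantile normalisation (13806 against 13509), in MZB without knockout 1 (360 against 357) and in FoB without knockout 2 (187 against 154). Outside the fits without 1 library, 1718 values for single regions or lists kept their status, called or not called, while 127 lost a call and 4 gained one. Of the main counts and shares 117 stayed and 50 moved (by more than 1.5 times for a count, out of the exact binomial interval for the share of opposite signs). The planned motif and promoter tests were not run. Depth limits low regions, where 3 reads make 0.2891 to 0.9464 rppm, and the cause was not tested where none is named.

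Quantile normalisation gave 780 higher and 474 lower in MZB, 187 and 122 in FoB, 13509 and 12246 higher between wild-type and knockout cell types, 4 for the difference between cell types and 90.3% opposite signs. A 2-fold threshold, which is stricter by construction, gave 196 and 158 in MZB, 122 and 83 in FoB, 14474 and 1410 between wild-type and 13868 and 998 between knockout cell types, 75 shared calls, 91.4% opposite and 0 for the difference. DESeq2 gave 122 and 48 in MZB, 104 and 52 in FoB, 13119 and 11848 higher between cell types, 57 shared calls and 92.5% opposite, with no adjusted p for 33077 regions in MZB and 27855 in FoB. Lower regions in MZB numbered 128 with a pseudocount of 0.1, 548 with 2 and 490 with compared groups only, which gave 127 and 85 in FoB. Lower regions between wild-type and knockout cell types numbered 15986 and 14160 with median-of-ratios scaling and 17052 and 14695 in edgeR with TMM. The difference between cell types counted 0 with a pseudocount of 0.1 or outside the enriched bins, 2 in edgeR with or without TMM, 3 with median-of-ratios scaling or robust shrinkage and 5 with a pseudocount of 2 or the block by genotype and number. List calls in the knockout comparisons, 3 with the preset correlation, numbered 1 with an estimated one and 5 with median-of-ratios scaling or a filter at 3 rppm. NK cell markers in MZB passed with a pseudocount of 0.1 (adjusted p = 0.0491), that filter (0.0448) and median-of-ratios scaling (0.0418). Shared calls outside the enriched bins numbered 60, and the share of opposite signs against the knockout libraries was 50%, by other shared libraries.

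Whether samples of the same number share an animal is open. Over all regions the deviations of MZB and FoB of one genotype and number correlated at -0.073 to 0.068. Knockout and wild-type samples of the same number, which cannot share an animal, correlated at -0.093 to 0.13. Not every sample correlated best with its own number. Over called regions of the enriched bins of single chromosomes, MZB and FoB of the same number and genotype correlated at -0.86 to 0.75. All 3 wild-type pairs of the same number exceeded all others on chromosome 1 (0.11, 0.13 and 0.15, highest of others -0.0076, 91 regions) and chromosome 12 (0.66, 0.61 and 0.75, highest of others 0.1, 8 regions), as the knockout pairs did on no chromosome. A replicate block gave 475 and 271 regions in MZB, 302 and 221 in FoB, 21785 and 10261 between wild-type and 20863 and 8505 between knockout cell types, and 2 in place of 1 for the difference. Among named regions Ets1 in FoB missed the threshold with the block, which changed no other call.

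Leaving out 1 library in turn gave 204 to 357 higher and 83 to 360 lower in MZB, 147 to 363 and 96 to 187 in FoB, 18466 to 19578 and 8263 to 8961 between wild-type and 17067 to 18953 and 6848 to 7908 between knockout cell types, 0 to 4 for the difference, 96 to 140 shared calls, 79.8% to 90.1% opposite and 2 to 4 list calls (2 without FoB knockout 1 or 2). The Kdm1a region passed between knockout cell types without MZB knockout 1 (log2 fold change 0.441, adjusted p = 0.0347). Of the named regions 36 lost their call in DESeq2, 12 with compared groups only, 12 with a pseudocount of 0.1, 4 with 2, 7 with quantile normalisation, 7 in edgeR with TMM, 10 without it and 7 with robust shrinkage, which took Steap3 and Cnr2 in both cell types.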

Other observations

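The test of splits for the difference between cell types was chosen only after the result was seen. On chromosome 12 a short stretch rose in both cell types in knockout libraries. Regions at Fam177a, Srp54b, Fam177a2 and Srp54c, chosen after their values were seen, had log2 fold changes of 0.99, 1.06, 0.93 and 0.99 in MZB and 0.90, 0.91, 0.82 and 0.86 in FoB, and limma called each in both. These genes are near-identical copies and can share reads, so the values are uncertain. Most calls of the enriched chromosome 12 bin lay in this stretch, from 55124160 to 55239170. A copy number change of the stretch was not tested.

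Regions of immature and transitional B cell markers did not move alike. The median log2 fold change in knockout MZB was 0.48 over 36 regions at Sox4, 0.41 over 13 at Cd93, 0.39 over 9 at Spn, which encodes CD43, and 0.29 over 18 at Erg, an ETS factor gene. It was 0.19 over 23 regions at Lef1, 0.11 over 23 at Myb, 0.047 over 25 at Cd24a and 0.036 over 9 at Dntt, which encodes the terminal transferase of early B cells. A general shift of MZB regions toward the FoB level might raise this list, which is lower in wild-type MZB than FoB. Random lists matched on level and on the difference between cell types had a median of 0.049 and a highest value of 0.17 in 10000 draws. Against 0.26 observed, 100% of them lay lower. The draws took regions singly, while the regions of this list gather at a few genes and can move together. Their spread is therefore too narrow, and the test cannot decide whether a general shift is the whole source.

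Other splits of the libraries of each comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. For knockout MZB 1 of 10 splits called as many regions as the real 698 (highest other 1), for knockout FoB 1 of 10 (484, highest other 37), for wild-type cell types 1 of 10 (32026, highest other 0) and for knockout cell types 1 of 10 (29349, highest other 0). For the difference between cell types, the knockout effect common to both was first subtracted, so that it could not enter other splits. Then 9 of 100 splits called at least the real 1 region, so chance cannot be excluded for this count. The highest of the others called 102, which points to a structure of the samples whose source was not tested.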
